A study of Mus musculus with 6 samples.

How the data were processed

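Expression was measured on Affymetrix Gene 1.0 ST arrays in 6 samples of jejunal epithelial cells from mice, 3 titled control and 3 titled transgenic, which the labels call biological replicates. The transgenic samples are called MSI2-induced here after their stated genotype. All mice received doxycycline for 24 hours. The values used were deposited by the authors as log2 expression per probe set, 1 column per array with nothing pooled. The scale was read from the values and from the submitters' processing notes, which name Partek and RMA without versions or settings. RMA corrects background, normalizes between arrays and summarises the probes of a probe set, so a global shift in RNA amount is removed and small changes of dim probe sets are compressed. Background flags and probe positions were not used here, and the genome build is not given in the sources used here.

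The table held 28350 probe sets, of which 21780 named 1 gene, 1618 named several and 4952 were unnamed here. Symbols were updated through gene identifiers with a RefSeq table of assembly GRCm38.p6, which matched 21689 of the 21780. That table served only for names and for the order of neighbouring genes. Each gene was represented by the 1-gene probe set with the highest mean over the 6 arrays, giving 19933 genes, of which 996 had more than 1 probe set. No filter on dim probe sets was applied.

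Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 fold changes are MSI2-induced minus control, and standard errors are the moderated ones. Gene lists were fixed before the data were examined, and 40 lists with at least 4 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 40 lists. An estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were alternatives. Counts adjusted over the list alone used Benjamini-Hochberg within each list. Lists that hold the same gene are not independent.

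Named genes followed a rule fixed before the data were examined. It took Msi2 and Msi1, and the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping groups and established symbols. From each list that passed in camera it took the 4 members with the lowest p, and from the other lists up to 2 members past the threshold. It also took 16 genes of intestinal stem cells, lineages and Musashi targets regardless of their values, 1 of which is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

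The groups share replicate numbers. Deviations from the group means correlated across genes by 0.52, 0.41 and 0.13 for the pairs numbered 1, 2 and 3. Such deviations cancel out within each group, so these correlations are not independent and do not establish a pairing. No label says what a number shares. The main fit had group as its only term, and the replicate number entered as a block only in an alternative. Control replicate 3 correlated more with MSI2-induced replicate 2 (0.32) than with its own number. The sex of each animal was read from Xist and the Y-linked genes Uty, Eif2s3y and Kdm5d. Control replicates 1 and 3 and MSI2-induced replicate 3 were female and the other 3 animals male. Control replicates 2 and 3 correlated by 0.996 over all probe sets but differed in sex, so they came from different animals. Control replicate 1 correlated with them by 0.981 and 0.982. The first principal component held 73.6% of the variance and separated the groups, and the second held 14.7% and set control replicate 1 apart.

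The fits were tested on simulated data with 19933 genes, 200 of them changed, drawn from the real means and spreads, beside a 20-gene list shifted by 0.5. Of the genes changed by 1 log2 unit 77% were recovered, of those changed by 2 log2 units 92%, with 12 false calls, and the shifted list passed in camera. Simulated genes varied independently, and no simulated array was set apart as control replicate 1 was. The real lists had estimated correlations of up to 0.93. The simulation therefore does not test camera on lists whose genes move together, nor the false calls under a deviating array. The alternatives were the replicate block, the mean of all probe sets of a gene, 2 filters on the mean, renewed quantile normalization, median centring, an intensity trend with and without robust estimation, array weights, other thresholds, all probe sets, and leaving out each array in turn. Sex as a block and list counts without control replicate 1 were added after the data were seen. Probe sets naming several genes entered only the fit over all probe sets.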

Results

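MSI2 is a Musashi-family RNA-binding protein that binds messenger RNAs and alters their translation or stability. Gene expression was measured in primary epithelial cells isolated from the mouse jejunum, a middle segment of the small intestine. The 3 control mice carried the M2rtTA transactivator at the Rosa26 locus, which drives tetracycline-responsive transgenes when doxycycline is present. The 3 other mice carried the same transactivator together with a tetracycline-responsive MSI2 transgene and, titled transgenic by their labels, are called MSI2-induced here. All 6 mice drank doxycycline for 24 hours before the cells were isolated. Each mouse gave 1 Affymetrix Gene 1.0 ST array, and the number of arrays limits the precision. The comparison asks which transcripts differ in the epithelium 1 day after MSI2 induction. The 28350 probe sets had array medians between 6.42 and 6.46 on the log2 scale.

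The transcript of the induced gene was examined first, since it checks the labels. Msi2 had a mean of 11.08 ± 0.45 (SD, n = 3) in the arrays labelled transgenic and 10.05 ± 1.09 (SD, n = 3) in the controls. The log2 fold change was 1.03 with a standard error of 0.55, and it did not pass in limma (adjusted p = 0.257). An exact two-sided permutation test of this value gave p = 0.3, where 0.1 is the smallest p that 3 against 3 arrays allow. Control replicate 1 had an Msi2 value of 11.30, which lay with the values of 11.23, 10.58 and 11.44 in the MSI2-induced arrays and above the 9.53 and 9.32 of the other controls. Without that array the log2 fold change of Msi2 was 1.66 with an adjusted p of 0.00958. The paralog Msi1 was 50.7-fold higher in the arrays labelled transgenic, with means of 13.26 ± 0.39 against 7.60 ± 0.38 (SD, n = 3 each). Its log2 fold change of 5.66 passed in limma (adjusted p = 0.000818), and its exact permutation test gave the smallest possible p of 0.1. Control replicate 1 had a control-level Msi1 value of 7.20. Each of these 2 genes was read by 1 probe set. The Msi2 probe set therefore did not separate the libraries by their labels, and all directions below are drawn between the libraries labelled transgenic and those labelled control.

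**Figure D1:**
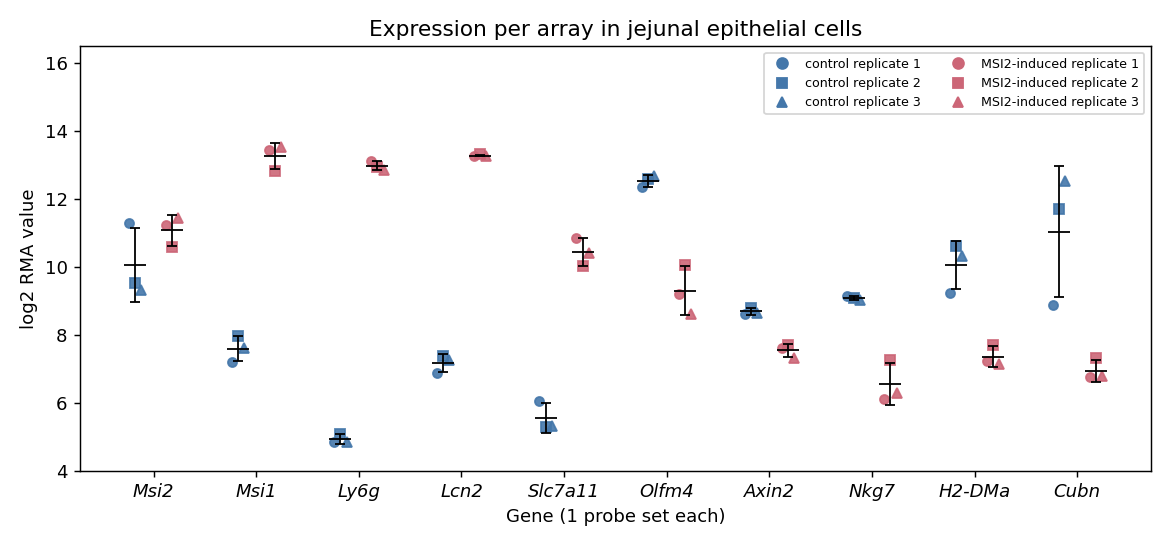
Log2 RMA value (vertical axis) of 10 genes (horizontal axis) in each of the 6 arrays, with symbols for replicates, colours for groups, long bars for group means and error bars of 1 SD (n = 3). Msi2 of control replicate 1, at 11.30, lies among the MSI2-induced values, while Msi1, Ly6g and Lcn2 separate the groups by 5.66, 8.06 and 6.11 log2 units.

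The libraries labelled transgenic differed from the controls most in Ly6g, a glycosylphosphatidylinositol-anchored surface protein of the Ly6 family, whose level was higher (log2 fold change 8.06, SE 0.11, adjusted p = 5.09e-06). Plat, which encodes tissue plasminogen activator, rose by 6.25 on the log2 scale, and the siderophore-binding protein gene Lcn2 by 6.11. Of the 3 control values of Ly6g and of Plat, 2 each lay in the range of 4.07 to 5.06 that Xist and Y-linked probe sets showed in animals lacking those transcripts, and the third lay above it, at 5.09 and 5.28, so the size and rank of these rises are uncertain. Next came Msi1 and the Ly6-family gene Gml at 5.22, followed by Lrg1, a secreted leucine-rich glycoprotein, at 5.21. Tat, the tyrosine aminotransferase, and the formin Fmnl2 both rose by 4.96, the cystine-glutamate antiporter Slc7a11 by 4.87 and the small proline-rich protein gene Sprr2f by 4.83. The largest falls were those of the apolipoprotein L gene Apol10a, with a log2 fold change of -4.28, and of Cubn, the receptor for the vitamin B12-intrinsic factor complex, with -4.09. The mitochondrial arginase Arg2 had a log2 fold change of -3.84, the gasdermins Gsdmc2 and Gsdmc4 had -3.77 and -3.55, and Sema4g had -3.41. The mitochondrial carrier gene Slc25a45 followed with -3.32, Igsf9 with -3.30, the carnosine dipeptidase Cndp1 with -3.25 and Olfm4, a marker of crypt base cells, with -3.24. All 3 values of Gsdmc4 and 1 of Cndp1 in the MSI2-induced arrays lay in that range too, so their falls could be larger. The Ly6, Gml, Sprr2 and Gsdmc genes have close relatives that could share probes, so their single-gene values are uncertain.

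Of 19933 genes tested, 1787 were higher and 1923 lower in the libraries labelled transgenic at an adjusted p under 0.05 in limma. All of these 3710 genes had non-overlapping groups, as did 37.0% of all genes, where chance gives 10%. At least 2-fold differences were found for 714 of the higher and 715 of the lower genes. The total was 5542 without control replicate 1, 7072 with array weights and 5139 with the replicate block. It was 976 without control replicate 2, 952 without control replicate 3, 1370 without MSI2-induced replicate 1 and 1074 without MSI2-induced replicate 3, and 2159 with the sex of the animals as a block, an alternative chosen after the data were seen. A fit with 1 array left out holds fewer arrays and so has less power. Without control replicate 2 or 3, control replicate 1, which stood apart, weighs more in the control group. A call lost in such a fit therefore need not mean a changed effect. Of the 20 genes with the largest rises and falls, Cubn, Gsdmc2, Gsdmc4, Sema4g and Slc25a45 lost their call without at least 1 array, with highest adjusted p values of 0.109, 0.0593, 0.0728, 0.0586 and 0.0828 without MSI2-induced replicate 3, control replicate 2, MSI2-induced replicate 3, control replicate 3 and control replicate 3, in that order.

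Lists of lymphocyte and antigen presentation transcripts were lower in camera in the libraries labelled transgenic, but not with an estimated correlation (adjusted p = 0.991 for both). Of 17 measured genes of T cells and intraepithelial lymphocytes, 13 fell and none rose, and 14 fell when p values were adjusted over the list alone. Among them Nkg7, a cytotoxic granule protein gene, had a log2 fold change of -2.53 ± 0.30 (SE), Itgae, the integrin that binds epithelial E-cadherin, -1.85 ± 0.20, Cd8a -1.54 ± 0.25 and Cd160 -0.84 ± 0.14. The list had a median log2 fold change of -1.35 and passed in camera (adjusted p = 8.66e-08, and 0.991 with an estimated correlation). Of 12 antigen presentation genes, 7 fell and none rose, and 11 fell when adjusted over the list alone. Examples were H2-DMa, which loads peptide onto class II molecules, at -2.70 ± 0.37, the peptide transporter Tap1 at -1.998 ± 0.24, and the immunoproteasome subunits Psmb9 at -1.56 ± 0.10 and Psmb8 at -1.51 ± 0.12. This list also passed (adjusted p = 7.84e-07, and 0.991 with an estimated correlation). Of 23 interferon response genes, 6 fell and Mx1, an antiviral GTPase gene, rose by 1.21 ± 0.14, with 10 falling and 1 rising when adjusted over the list alone. Irf1 was at -1.65 ± 0.22 in the probe set used and at -0.26 in its other probe set, Stat2 at -1.18 ± 0.16 and the RNA sensor Ddx58 at -1.70 ± 0.27, and the list passed in camera (adjusted p = 0.00103), but neither with an estimated correlation (adjusted p = 0.991) nor in fry (adjusted p = 0.174). With the replicate number as a block 11 antigen presentation genes and 11 interferon genes fell, and with sex as a block 7 lymphocyte genes and 4 interferon genes fell. The lymphocyte transcripts moved in the same direction as the antigen presentation and interferon lists. Cd8a, Cd160 and Ddx58 lost their gene-level call without at least 1 array, with highest adjusted p values of 0.0604 without MSI2-induced replicate 3 and of 0.0624 and 0.0563 without control replicate 3.

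The lists of amino acid supply, ribosome biogenesis, immediate early, unfolded protein response and p53 target genes were higher as lists in camera, but not with an estimated correlation (adjusted p = 0.991 for each). In the amino acid and ATF4 response list, 15 of 21 genes rose and 1 fell, or 17 and 1 when adjusted over the list alone. Besides Slc7a11, the lipoprotein receptor gene Vldlr rose by 2.03 ± 0.20 (SE) and Sesn2, an inhibitor of mTORC1 signalling, by 1.31 ± 0.14. The member that fell was Aldh18a1, an enzyme of proline synthesis, with -1.24 ± 0.15. All 25 genes of the ribosome biogenesis and MYC target list had higher means, 9 rose, and 23 rose when adjusted over the list alone. Odc1, the first enzyme of polyamine synthesis, rose by 1.09 ± 0.16, and the nucleolar genes Rrs1, Nop14 and Ddx21 rose by 1.48 ± 0.30, 1.27 ± 0.26 and 1.54 ± 0.33. With the replicate number as a block, 23 genes of this list rose. Myc itself rose by 1.79 ± 0.37. Of 18 immediate early genes, 8 rose and none fell, or 9 when adjusted over the list alone, with Klf6 at 2.02 ± 0.22, Zfp36 at 1.498 ± 0.23, Fosl1 at 3.42 ± 0.53 and Atf3 at 1.79 ± 0.31. Of 17 unfolded protein response genes 3 rose, or 6 when adjusted over the list alone, and these were the chaperone cofactor Dnajb9 at 1.17 ± 0.12, the chaperone Hspa5 at 0.73 ± 0.11 and Creld2 at 0.74 ± 0.16. Pdia6, at 0.63, did not pass over all genes (adjusted p = 0.0595), but did with the replicate block (adjusted p = 0.0388), where 5 members passed, and without control replicate 1 (adjusted p = 0.004). Of 15 p53 targets, 6 rose, or 8 when adjusted over the list alone, among them the apoptosis gene Pmaip1 at 2.88 ± 0.31, Plk2 at 2.19 ± 0.42, Zmat3 at 0.67 ± 0.13 and the death receptor Tnfrsf10b at 0.41 ± 0.09.

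These 5 lists passed in camera with adjusted p values of 9.21e-07 for amino acids and ATF4, 1.66e-07 for ribosome biogenesis, 0.00203 for immediate early, 0.0069 for unfolded protein response and 0.01 for p53 targets. None passed with an estimated correlation (adjusted p = 0.991 for each), and in fry only the amino acid list did (adjusted p = 0.0237). Control replicate 1 stood apart from the other controls in the ribosome list, with a median 1.09 log2 units above them, and without it 25 members rose. Without it, 6 unfolded protein response genes rose and 1 fell. With sex as a block, 8 amino acid genes, 4 ribosome genes, 2 unfolded protein response genes and 2 p53 targets rose. The unfolded protein response call was lost without MSI2-induced replicate 2 (adjusted p = 0.114). With 1 array left out, the calls of Rrs1, Nop14, Ddx21, Odc1 and Myc were lost at adjusted p values of up to 0.0921, 0.0962, 0.104, 0.0536 and 0.0947, each without MSI2-induced replicate 3. Those of Zfp36, Fosl1, Atf3, Creld2, Plk2, Zmat3 and Tnfrsf10b were lost at up to 0.0555, 0.0574, 0.0619, 0.101, 0.0852, 0.0789 and 0.113 without control replicate 3, and that of Hspa5 at 0.0567 without control replicate 2.

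**Figure D2:**
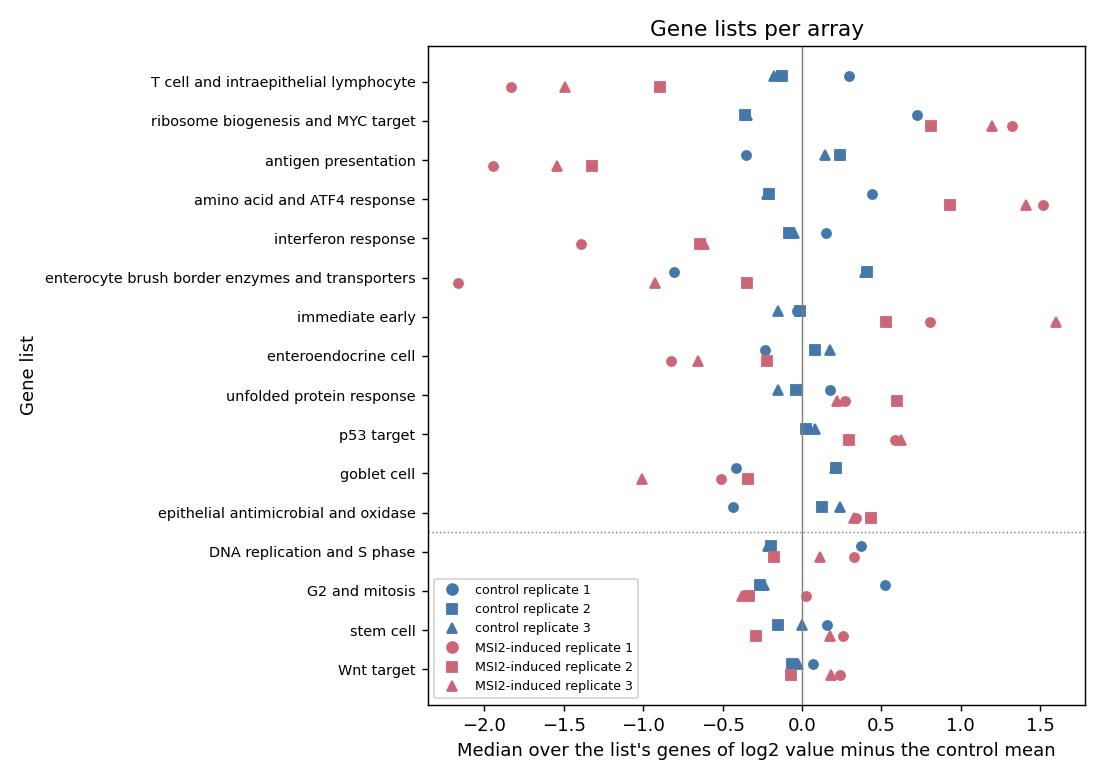
Median over the measured genes of each list of the log2 value minus the control mean (horizontal axis) in each of the 6 arrays, for the 12 lists that passed in camera (above the dotted line) and 4 that did not (below it). Colours stand for groups and symbols for replicates, and in the lymphocyte list the MSI2-induced arrays lie between -1.83 and -0.89 while the controls lie between -0.18 and 0.29.

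Among the lists of differentiated epithelial cells, enterocyte brush border genes were lower as a list in camera but not with an estimated correlation (adjusted p = 0.00118 and 0.996), and few passed singly. Of 23 measured genes, Cubn and the actin-bundling villin gene Vil1 (-0.80 ± 0.21, SE) fell, and Nt5e, which makes adenosine from AMP, rose by 2.26 ± 0.56, while no gene passed when adjusted over the list alone. The fructose transporter Slc2a5 was at -2.24 ± 0.69 and did not pass (adjusted p = 0.071). With the replicate number as a block, 16 of the 23 genes fell, Slc2a5 and the alkaline phosphatase Alpi among them (adjusted p = 0.00255 and 0.0253). Alpi, at -0.57, did not pass without the block (adjusted p = 0.444) or with sex as a block (adjusted p = 0.525). Relative to the control mean, the list's median was -2.16 in MSI2-induced replicate 1, -0.34 in replicate 2 and -0.93 in replicate 3, and control replicate 1 had a median of -1.21 relative to the other controls. Without control replicate 1, 7 genes of the list fell, Slc2a5 among them (adjusted p = 0.0228). The list did not pass in fry either (adjusted p = 0.373). Of 19 enteroendocrine genes 4 fell, also when adjusted over the list alone, namely the lineage factor Neurog3 at -0.74 ± 0.14, Chgb at -0.85 ± 0.19, Insm1 at -0.32 ± 0.07 and the proglucagon gene Gcg at -1.75 ± 0.47, while 7 fell with the replicate block and 9 without control replicate 1. With sex as a block, none of the brush border or enteroendocrine genes passed. Of 13 goblet cell genes none fell, against 2 with the replicate block and 3 without control replicate 1, and Fut2, a fucosyltransferase that the list holds, rose by 3.28 ± 0.54, also when adjusted over the list alone. Its other members had lower means, such as Tff3 at -1.07 ± 0.35 (adjusted p = 0.0833, and 0.0107 with the replicate block), Galnt12 at -0.86 ± 0.25 (adjusted p = 0.0638) and Creb3l1 at -0.61 ± 0.18 (adjusted p = 0.0686). Tff3 and Galnt12 passed without control replicate 1 (adjusted p = 0.0266 and 0.00766).

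The enteroendocrine and goblet lists passed in camera with adjusted p values of 0.00203 and 0.0376, and neither did with an estimated correlation (adjusted p = 0.991 for both) or in fry (adjusted p = 0.162 and 0.335). The goblet call was lost without control replicate 2, control replicate 3 or MSI2-induced replicate 3 (adjusted p = 0.0781, 0.0607 and 0.174). Of 17 epithelial antimicrobial and oxidase genes, 6 rose and 1 fell, also when adjusted over the list alone. Besides Lcn2 these included the cornified envelope gene Sprr1a at 3.29 ± 0.14 (SE), the antimicrobial lectin Reg3a at 3.06 ± 0.28 and S100a9 at 1.14 ± 0.16, and the member that fell was the immunoglobulin transporter Pigr, named after its value was seen, at -1.30. This list passed in camera (adjusted p = 0.0446) but not with an estimated correlation (adjusted p = 0.991), with the replicate block (adjusted p = 0.117), with sex as a block (adjusted p = 0.166), or without control replicate 1 or MSI2-induced replicate 2 (adjusted p = 0.347 and 0.0828). With 1 array left out, Vil1, Nt5e, Neurog3, Chgb, Insm1, Gcg and Fut2 lost their call at adjusted p values of up to 0.148, 0.139, 0.0717, 0.113, 0.115, 0.162 and 0.0563, without control replicate 2, MSI2-induced replicate 3, MSI2-induced replicate 1, MSI2-induced replicate 3, control replicate 3, MSI2-induced replicate 3 and control replicate 3 in that order.

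Stem cell and Wnt target genes moved in both directions, and neither list passed (adjusted p = 0.979 and 0.946). Of 17 stem cell genes 3 rose and 3 fell, or 4 and 3 when adjusted over the list alone, and 1 of the 3 risers was Msi1, whose signal is left open. Olfm4 was 9.48-fold lower, and the negative feedback gene Axin2 of the Wnt pathway and the stem cell transcription factor Ascl2 had log2 fold changes of -1.15 ± 0.12 and -1.14 ± 0.14 (SE). Lgr5, the receptor that marks crypt base stem cells, was at -0.84 ± 0.35 and did not pass (adjusted p = 0.154), but did with the replicate block (adjusted p = 0.0131). Of 18 Wnt targets 2 rose and 3 fell, or 4 and 3 when adjusted over the list alone. The risers were Myc and Cd44, at 1.82, which the stem cell list holds too. Axin2, Ascl2 and Ccnd1, at -0.53, fell. Cd44 and Ccnd1 were named after their values were seen. In the Notch list 3 of 17 genes rose and 5 fell, or 3 and 7 when adjusted over the list alone, and the list did not pass (adjusted p = 0.0598), but did without control replicate 3 (adjusted p = 0.0346) and with sex as a block (adjusted p = 0.0431). The Notch ligand Jag2 rose by 1.46 ± 0.13, and the effector Hes1 was at -0.53 ± 0.15 (adjusted p = 0.0631). The 5 members that fell were Olfm4, Nrarp at -1.09, Hes6 at -1.07, the receptor Notch1 at -0.63 and Dtx1 at -0.63. Beside Jag2, Jag1 and the receptor Notch2, at 0.94, rose. Nrarp, Hes6, Notch1, Dtx1 and Notch2 were named after their values were seen. Of 29 S phase genes 3 fell, also when adjusted over the list alone, with the thymidine kinase Tk1 at -1.01 ± 0.12 and E2f1 at -0.60 ± 0.08. Of 29 mitotic genes Cdca3 fell by 0.92, and none passed when adjusted over the list alone. Neither cell cycle list passed (adjusted p = 0.913 and 0.123), and Mki67, a proliferation marker, was at -0.25 ± 0.28 (adjusted p = 0.606). The mitotic list passed as lower without control replicate 2, control replicate 3 or MSI2-induced replicate 1 (adjusted p = 0.0087, 0.0112 and 0.0109), but not without control replicate 1 (adjusted p = 0.885). Control replicate 1 lay above the other controls in both, by medians of 0.56 and 0.79. Without that array 7 S phase genes rose and 3 fell, and 4 mitotic genes rose and 1 fell, while with the replicate block 2 S phase genes rose and 5 fell, and 3 mitotic genes rose and 6 fell. The call of Cdca3 was lost without MSI2-induced replicate 3 (adjusted p = 0.0871). Of 6 transcripts reported as Musashi targets, the Notch ligand Jag1 rose by 1.06 ± 0.25, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.458). The Jag1 call was lost without control replicate 3 (adjusted p = 0.115), and 2 of the 6 rose with the replicate block but none with sex as a block (Jag1 adjusted p = 0.0528). With sex as a block 1 Notch gene rose and 5 fell, and no mitotic gene passed. Numb passed without control replicate 1, at -0.39 (adjusted p = 0.0202). Of 6 genes of reserve stem cells, Clu rose by 1.55 and the telomerase gene Tert fell by 0.81, or 2 rose and 2 fell when adjusted over the list alone (list adjusted p = 0.979). No call was made for Atoh1, Lrig1, Bmpr1a, Numb, Muc2, Lyz1 or Chga, whose log2 fold changes were -0.67, 0.36, 0.06, -0.20, -0.69, -0.03 and -0.88 with adjusted p values of 0.254, 0.502, 0.782, 0.493, 0.374, 0.83 and 0.0977. Cdkn1a had no probe set of its own, and a probe set that it shares with another gene had a log2 fold change of 1.08 (adjusted p = 0.0389 over all probe sets), which cannot be assigned to either gene.

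Metabolic lists did not pass either, although single members changed. Of 14 fatty acid synthesis genes 3 fell, also when adjusted over the list alone, with the desaturases Fads1 and Fads2 at -1.84 ± 0.11 and -1.71 ± 0.13 (SE), and the list had an adjusted p of 0.0919, but passed without control replicate 2 or control replicate 3 (adjusted p = 0.0136 and 0.0387). It did not without control replicate 1 (adjusted p = 0.595) or with the replicate block (adjusted p = 0.155). Of 17 glycolysis and hypoxia genes 3 rose and 1 fell, or 4 and 1 when adjusted over the list alone, with the hexokinase Hk2 at 2.89 ± 0.28 (list adjusted p = 0.979). Of 22 xenobiotic and NRF2 genes 2 rose and 3 fell, or 3 and 5 when adjusted over the list alone. In that list the carboxylesterase Ces2a was at -2.16 ± 0.26 and the glutathione transferase Gstm3 at -3.20 ± 0.40, with -3.87 in its other probe set. The xenobiotic list passed with the replicate block (adjusted p = 0.252 without it and 0.0427 with it), as did the enterocyte lipid absorption list (adjusted p = 0.189 and 0.0219), which also passed without control replicate 1 (adjusted p = 0.0194). These calls used camera's preset correlation. With an estimated correlation, in the fit without the block, both lists had an adjusted p of 0.996. Without the block, only the triglyceride-forming enzyme Dgat1 fell among the 20 lipid absorption genes, by 1.72, a call lost without control replicate 3 (adjusted p = 0.147), and none passed when adjusted over the list alone. With the block, 2 of these 20 genes rose and 10 fell, while 6 fell without control replicate 1 and none passed with sex as a block (Dgat1 adjusted p = 0.0892). Of the xenobiotic genes 2 rose and 7 fell with the block, 4 rose and 9 fell without control replicate 1, and 2 rose and 3 fell with sex as a block. In the circadian clock list, 4 of 16 genes rose and 3 fell, or 5 and 4 when adjusted over the list alone, with the repressor Cry1 at 1.51 ± 0.13 (list adjusted p = 0.946). The glucocorticoid and gluconeogenesis list, which holds Tat, had 3 of 13 genes up and 2 down, or 4 and 2 when adjusted over the list alone (list adjusted p = 0.633). Of 20 cholesterol synthesis genes 2 rose and 2 fell, or 2 and 3 when adjusted over the list alone, and Hsd17b7 rose by 1.25 (list adjusted p = 0.973). Of 19 fatty acid oxidation and PPARA target genes 3 rose and 3 fell, or 5 and 5 when adjusted over the list alone, and the dehydrogenase Acadl rose by 0.83 (list adjusted p = 0.979). Of 17 genes of NF-kappaB signalling and chemokines 3 rose and 1 fell, also when adjusted over the list alone, with the adhesion molecule Icam1 and the inhibitor Nfkbia up by 1.36 and 1.25 (list adjusted p = 0.831). Of 13 heat shock genes 2 rose and 1 fell, also when adjusted over the list alone, with the cochaperone Bag3 up by 1.16 (list adjusted p = 0.633). With the replicate block, 5 cholesterol genes rose and 3 fell, 6 fatty acid oxidation genes rose and 5 fell, 4 glycolysis genes rose and 3 fell, 4 NF-kappaB genes rose and 3 fell, and 5 glucocorticoid and gluconeogenesis genes rose and 2 fell. The counts of these 5 lists, in that order, were 4 and 3, 4 and 7, 3 and 2, 3 and 3, and 4 and 2 without control replicate 1, and 1 and 0, 3 and 1, 3 and 0, 2 and 0, and 3 and 2 with sex as a block. Of the heat shock genes 4 rose and 1 fell without control replicate 1, and 1 rose and 1 fell with sex as a block, where 3 clock genes rose and 1 fell. Further members of these lists passed but lost their call without control replicate 3, namely Fbp1 at -2.23, Msmo1 at 0.74, Pgk1 at 0.64 and Acot2 at 2.51 (adjusted p = 0.0582, 0.101, 0.0514 and 0.0563), or without control replicate 2 or MSI2-induced replicate 3, namely Hspa4l at -0.47 and Nfil3 at 1.57 (adjusted p = 0.0712 and 0.0764).

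Markers of other cells were checked in the same way. Of 16 myeloid genes 2 rose and 1 fell, also when adjusted over the list alone. Ly6g was 1 of the risers, and the Fc receptor chain Fcer1g fell by 0.86 (list adjusted p = 0.136, and 0.0236 without MSI2-induced replicate 3). Of 12 endothelial genes 2 rose, also when adjusted over the list alone, and the receptor Tie1 rose by 1.30 (list adjusted p = 0.946). Of 17 fibroblast and smooth muscle genes 2 fell, also when adjusted over the list alone, and Mylk fell by 0.70 (list adjusted p = 0.99). None of 16 tuft cell, 12 B and plasma cell, 9 enteric neuron and glia, and 10 exocrine pancreas genes passed in limma, over all genes or over each list alone, and the tuft list passed as lower only without MSI2-induced replicate 3 (adjusted p = 0.0396). Lyve1 rose by 0.91 and Vim fell by 0.89, calls lost without control replicate 2 and MSI2-induced replicate 3 (adjusted p = 0.0759 and 0.0892). None of 5 sex-linked genes passed. Of 18 Paneth cell genes fixed for the list only 8 were measured, so its result leaves the others open. Of the 8 measured only Nupr1 rose, a stress gene that the amino acid and ATF4 list holds too, by 1.43 (list adjusted p = 0.946), and it lost its call without control replicate 3 (adjusted p = 0.128). Among regional markers, the distal bile acid transporter Slc10a2 rose by 2.96 and the transcription factor gene Osr2 fell by 2.08, and neither the distal list of 7 genes nor the proximal list of 8 passed (adjusted p = 0.916 and 0.831). The call of Slc10a2 was lost without control replicate 2 (adjusted p = 0.0809). With the replicate block 2 proximal genes fell and 2 distal genes rose and 2 fell, and with sex as a block 1 fibroblast and smooth muscle gene fell and no Paneth cell gene passed. Of 40 lists tested, 12 passed in camera and 28 did not, and 8 of the 28 had a median, mean and test that differed in sign.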

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

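Sex as a block, and the list counts without control replicate 1 that the results give, were chosen after the data were seen. Of the 96 named genes that passed, all kept their direction in every alternative in which they were tested, 96 stayed past the threshold with the replicate block and 55 in all 6 fits with 1 array left out. With 1 array left out the count of changed genes ranged from 952 to 5542, that of higher genes from 476 to 2663, that of lower genes from 476 to 2879 and the log2 fold change of Msi2 from 0.67 to 1.66. The lowest counts came without control replicate 3 (952) and control replicate 2 (976), and the highest without control replicate 1, where 3496 of the 5542 genes were shared with the 3710. With sex as a block 2159 genes passed, 1068 higher and 1091 lower, and 80 of the 96 named genes stayed past the threshold. The 16 others were Cubn, Nt5e, Vil1, Neurog3, Chgb, Insm1, Gcg, Creld2, Zmat3, Tnfrsf10b, Cdca3, Dgat1, Jag1, Nupr1, Msmo1 and Vim (adjusted p = 0.0523 to 0.0892). Array weights, which gave control replicate 1 the lowest weight (0.33), called 7072 genes, 3630 higher and 3442 lower, and Msi2 passed with a log2 fold change of 1.62 (adjusted p = 0.0129, within a range of 0.00958 to 0.553 over its alternatives). A looser adjusted p of 0.1 gave 2729 higher genes, by its construction. The replicate block gave 5139 genes, 2534 higher and 2605 lower. Beyond the calls and counts given with the results, it changed no other call of a named gene or list. Of the 12 lists that passed in camera, 9 passed in all 6 fits with 1 array left out, 0 passed with an estimated correlation and 4 passed in fry, which called 7 lists. It kept the lymphocyte, antigen presentation, amino acid and antimicrobial lists, ended the ribosome, interferon, brush border, immediate early, enteroendocrine, unfolded protein response, p53 and goblet calls (adjusted p = 0.0635 to 0.373), and added the Notch, myeloid and endothelial lists (0.0128 each). The Notch list was called lower, and the myeloid and endothelial lists higher. In the endothelial list 4 genes had higher and 8 lower means, with a median of -0.05, and only Tie1 and Lyve1 passed singly. In the myeloid list 13 genes had higher and 3 lower means, with a median of 0.18, and it holds Ly6g, whose value is uncertain. These 2 calls therefore do not show a shift of endothelial or myeloid transcripts as a group. The goblet list also lost its call with both filters on the mean, renewed quantile normalization and median centring (adjusted p = 0.0742, 0.137, 0.0833 and 0.0505), and the antimicrobial list with both filters and array weights (0.0742, 0.225 and 0.356). The enteroendocrine list lost its call above the median (0.0616). An estimated correlation widens camera's test where the genes of a list move together. The Notch list had an estimated correlation of -0.039, yet its adjusted p in camera went from 0.0598 to 0.991. Correlation within a list therefore does not alone account for the values with an estimated correlation. What else raised them, and the cause of the other changes, was not tested. No scaling moved the median log2 fold change of all genes beyond 0.03. Probe sets whose values lay between 4.07 and 5.06, the range of absent sex-linked transcripts, leave the size of a fold uncertain.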

Other observations

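All tests in this part except those of other groupings of the arrays were chosen after the result was seen, and so were the genes of this paragraph. The 4 tests on Msi1, Msi2 and Ly6g were reworded after first versions had been computed, 2 of which set levels of different probe sets against each other. Of 6 measured genes that encode ligands of the EGF receptor family 4 rose in limma, Ereg by 3.57, Btc by 3.21, Hbegf by 2.57 and Tgfa by 0.67, while Egf at 0.11 and Epgn at 0.26 did not pass (adjusted p = 0.547 and 0.0548). Of 12 annexins, which bind membrane phospholipids in the presence of calcium, 6 rose and 1 fell. Anxa1, Anxa3 and Anxa10 rose by 4.46, 3.97 and 3.76, and Anxa6 fell by 0.39, with -0.05 in its other probe set. In the plasminogen and tissue factor system 3 of 8 genes rose. Beside Plat these were Plaur, the urokinase receptor, by 4.21 and F3, which encodes tissue factor, by 4.67, and Plau, which encodes urokinase, was at 0.27 (adjusted p = 0.169). Of 15 genes linked to epithelial injury responses 7 rose, such as the interleukin 1 receptor antagonist Il1rn by 3.54 and Il33 by 2.50, whereas Ccn1 and Ccn2 were at 1.85 and 1.63 and did not pass (adjusted p = 0.077 and 0.0811). Ereg, Anxa1 and Anxa2 count in 2 of these lists.

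Msi1 was 5.66 log2 units higher in the libraries labelled transgenic, while Msi2 was 1.03 units higher (1.031) and did not pass. The change of Msi1 exceeded that of Msi2 by 4.63. On the linear scale the group mean went from 198 to 10045 for Msi1 and from 1301 to 2235 for Msi2. The control mean of Msi2 includes the high value of control replicate 1. Different probe sets can respond unequally, so these gains do not test whether unequal control values account for the difference. Whether the Msi2 probe set reads the transgene is not known. The difference therefore does not test whether transcripts of the transgene bound the Msi1 probe set. Probe positions were not used here, and that explanation stays open. Animals carrying another transgene than the labels name, and an induction of the endogenous Msi1 gene, cannot be told apart by the Msi2 value, since both allow a small change of Msi2. The effect of MSI2 itself stays open, as untested.

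Control replicate 1 stood apart from the other 2 controls, with an Msi2 value like that of the MSI2-induced arrays. The sex of the animal is argued against as the cause, since over the genes without sex-linked ones control replicate 1 differed from control replicate 3, an animal of the same sex, 2.6 times as much as control replicate 2 did (root mean square). Among the 5542 genes called without it, control replicate 1 lay nearer to the MSI2-induced mean in 41.6%, and with Msi1 at 7.20 and no MSI2-induced array at a control level, an exchange of labels is argued against. A smaller share of villus cells in that preparation is a candidate explanation: at least 96.6% of the members lay on the side it needs in each of 4 lists, with brush border and lipid absorption genes lower (medians -1.21 and -0.86) and S phase and mitotic genes higher (0.56 and 0.79). Members of these 4 lists move together (estimated correlations of 0.67 to 0.85), so the percentages do not count independent genes. Outside the 4 lists, all 17 lymphocyte genes lay above the other controls (median 0.44). Of the 17 stem cell genes 10 lay above and 7 below (median 0.24). The 4 lists therefore do not settle the explanation. This was seen in 1 array, and a difference between animals in the epithelium itself stays open.

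The rise of Ly6g, a surface marker of neutrophils, could have come from neutrophils among the isolated cells. S100a8 and S100a9, which are abundant in neutrophils, had log2 fold changes of no more than 1.53 at the higher of their upper 95% bounds, against 8.06 for Ly6g, and the median of 14 neutrophil genes was 0.24. Of these 14, S100a9, Cxcr2 and Ltf rose, by 1.14, 0.83 and 0.38, and none fell. S100a9 is also in the epithelial antimicrobial list. Signal from related transcripts stays open: among 34 other probe sets of the Ly6 family the largest rise was 5.52, in a probe set shared by Gml and Gml2, and 2 probe sets shared by Ly6c1 and Ly6c2 rose by 5.31 and 4.64, but probe sequences were not used here. An expression of Ly6g by the epithelial cells is a further hypothesis that was not tested.

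A further hypothesis was that changed genes lie beside each other along the chromosomes. Among 19914 genes placed in order, 254 neighbouring pairs were both higher, against a mean of 160 over 10000 random placements (one-sided permutation p = 1e-04, the smallest these permutations can give). For lower genes there were 313 pairs against 186. Leaving out pairs whose symbols begin alike, which may share probes, 224 and 288 pairs were left against means of 137 and 158. Neighbours may also share regulation or cell type, which these counts do not separate. The random placements drew from all 19914 genes whatever their expression level. They therefore cannot tell the excess from a grouping of expressed genes along the chromosomes.

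The 6 arrays can be split into 2 groups of 3 in 10 ways, which is too few for a share under 0.05. Every other split mixes control and MSI2-induced arrays on both sides. The difference between the labelled groups then widens the spread within each side, which lowers gene counts. Part of it also stays between the sides and can move whole lists. The counts of the other splits are therefore not rates expected without a group difference. The real split gave 3710 changed genes and the highest of the others 4, so 1 of the 10 splits gave as many, and the 3 other splits that part all pairs gave 0. For gene lists, the real split gave 12 lists past the threshold, 5 of the 10 splits gave at least as many, the highest of the others gave 18, and the highest that parts all pairs gave 15.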
